A study of Mus musculus with 13 samples.

How the data were processed

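RNA of Neuro2a cells was sequenced by the submitters in 13 libraries: 3 control and 4 experimental libraries at passage 1, and 3 of each at passage 6. Per the labels, libraries were poly(A)-selected and stranded, from RNA with an integrity number above 7.0. The authors deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in 1 table per passage. Per the submitters' processing notes, cutadapt, HISAT2, StringTie, DESeq2 and edgeR were used with the mouse genome mm10, without versions, so how the FPKM were scaled between libraries is not stated. The tables hold the same 34857 Ensembl gene identifiers in the same order, of which 34731 matched a gene symbol in the GRCm38 annotation used here. All 13 value columns were used, a gene with 1 empty cell was left out, and 1212 genes were at 0 in every library. Coordinates are 1-based on GRCm38, the assembly also called mm10.

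Sequencing depth is unknown, because FPKM hold no read counts, so precision was taken from the spread between libraries. The labels do not state whether the replicates of a group are separate vials, dishes or RNA aliquots. The p-values therefore measure only the spread between these samples, which may be technical.

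Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and equal weights, separately for each passage. Genes with at least 1 FPKM in at least 3 libraries of the passage were tested two-sided, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. A gene is called changed, higher or lower where its adjusted p passes that threshold. Fold changes are 2 to the power of the fitted log2 change, and so include the added 1 FPKM, which makes them smaller than the ratio of mean FPKM at low levels. The difference between the passages was tested as a contrast over the 13 libraries, for genes passing the filter in at least 1 table. Control and experimental libraries share a passage, but passages 1 and 6 were deposited as separate tables, so only the change within each passage enters this contrast.

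Lists of genes were fixed before the data were examined, 39 in all, of which 33 with at least 5 tested members were tested at passage 1 with limma's camera, at a preset correlation between genes of 0.01, and again with an estimated correlation. Counts of changed genes in a list are given from adjustment over all genes and from adjustment over the list alone. The mitochondrially encoded, ribosomal protein, replication-dependent histone and nuclear-retained noncoding lists were fixed as checks of RNA quality. A change in them is therefore not read as a response of the cells. Overlap between passages was tested with a one-sided hypergeometric test. Library measures were compared with exact two-sided permutation tests in scipy 1.17.1, with p adjusted over 20 comparisons, and the smallest possible p is 0.0571 for 3 against 4 and 0.10 for 3 against 3 libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

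The genes named were chosen by a rule written before the data were examined: per passage, the 10 largest positive and negative changes among genes with adjusted p under 0.05, a mean of at least 5 FPKM, no overlap between the groups and an assigned gene name. Up to 4 called genes per list, or the 2 with the highest FPKM where none was called, were added, with Cirbp and Rbm3 always included. For the difference between passages 5 genes per direction were chosen in the same way, without the condition on overlap. The per-library values of the tissue markers, and the differences between passages for Acta2, Fkbp10 and Ccl2, were chosen after their values were seen.

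The fit was tested on simulated data with the group sizes of this study. The changed genes were drawn only from those with a mean log2(FPKM + 1) above that of 5 FPKM. Noise was normal with the spread of each gene, and independent between genes and libraries. The shares called therefore do not cover genes at lower FPKM. No rate below covers correlated genes or effects of single libraries. Of 100 genes given a log2 change of 0.5, 79% were called at passage 1, 74% at passage 6 and 60% for the difference between passages, and of 100 genes given a log2 change of 1, 99%, 95% and 90%. False calls made up 7.77%, 3.98% and 4.46% of all calls.

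Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter or a minimum of 5 FPKM, equal FPKM totals, median-of-ratios scaling and quantile normalization. They also were limma without trend or with robust settings, array weights, the replicate number as a block, 1 fit over both passages, camera with an estimated correlation, the rotation test fry and leaving out each library in turn. Other alternatives were chosen after seeing the data. Passage 6 experimental libraries 2 and 3 were left out together, which leaves 1 experimental library of that passage. The summed colon (and at passage 1 also cartilage) markers were used as covariates. At passage 6 the colon sum is far lower in experimental libraries 2 and 3 than in the rest. With that covariate the fitted change therefore rests mostly on experimental library 1 against the controls. Further alternatives were the passage 1 libraries with cartilage transcripts only and genes with at least 300 nt of exons. The last were an exact permutation of list medians and the test of gene lists on the difference between passages. Marker lists of 15 tissues or cell types were written after the data were seen: colon epithelium, liver, brain, cartilage, bone and connective tissue, smooth muscle, skeletal muscle, heart, kidney, lung, pancreas, testis, erythroid cells, lymphoid cells and Y-linked genes.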

Results

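Poly(A) RNA was measured in 13 libraries of Neuro2a, a mouse neuroblastoma cell line with neuron-like properties, to ask how cells that survived a failed cryostorage differ from cells that stayed frozen. Vials were frozen in 10% DMSO, a cryoprotectant. The experimental vials lost their liquid nitrogen over 10 h, stood for 24 h at 4 °C, were frozen again at -80 °C for 72 h and were thawed at 37 °C, while control vials stayed in normal storage until thawing. RNA was taken at passage 1, when the surviving cells proliferated again, and at passage 6, when they looked normal, each time with time-matched controls. There were 3 control and 4 experimental libraries at passage 1, and 3 of each at passage 6. The deposited values are FPKM for 34857 genes, so the number of reads behind each value is unknown and precision is judged from the spread between libraries alone.

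Between 12014 and 12467 genes reached 1 FPKM in a library. Correlations of log2(FPKM + 1) between libraries of one group lay between 0.976 and 0.995 at passage 1 and between 0.978 and 0.994 at passage 6, against 0.956 to 0.981 and 0.968 to 0.982 between control and experimental libraries. The first principal component separated the groups at both passages and held 54.8% and 60.3% of the variance. At passage 6 experimental library 1 lay at 1.81 on it, between the controls (-14.9 to -17.6) and experimental libraries 2 and 3 (24.6 and 22.9). Mitochondrial transcripts made up 14.7 ± 0.124% of FPKM in controls and 13.6 ± 1.03% in experimental libraries at passage 1 (exact two-sided permutation p = 0.171), and 27.3 ± 0.201% and 25.8 ± 0.881% at passage 6 (exact p = 0.10, the smallest that 3 against 3 libraries allow). The lowest adjusted p over the 20 exact comparisons of library measures was 0.190.

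Transcripts of tissues other than a neuroblastoma line were present in some libraries. Summed over 20 colon epithelium markers such as Krt8, Car1 and Zg16, they came to 468, 200 and 225 FPKM in the passage 1 controls, and to 189, 170, 2.04 and 78.9 FPKM in the experimental libraries. At passage 6 the sums were 112, 217 and 248 FPKM in controls, and 105, 2.91 and 2.62 FPKM in experimental libraries. Cartilage markers, led by the type II collagen gene Col2a1, summed to 7.21 FPKM in control 1 and 8.69 FPKM in experimental library 4 at passage 1, and to 32.3 to 50.9 FPKM in the other 5 libraries of that passage. At passage 6 they summed to 35.8, 44.4 and 60.7 FPKM in controls and to 18.6, 18.5 and 20.8 FPKM in experimental libraries, where Col2a1 itself was at most 0.325 FPKM. Liver markers such as albumin (Alb) summed to 252 and 205 FPKM, and brain markers such as the myelin gene Mbp to 106 and 83.3 FPKM, in passage 6 experimental libraries 2 and 3, against at most 2.06 and 15.5 FPKM in the other 11 libraries.

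**Figure D1:**
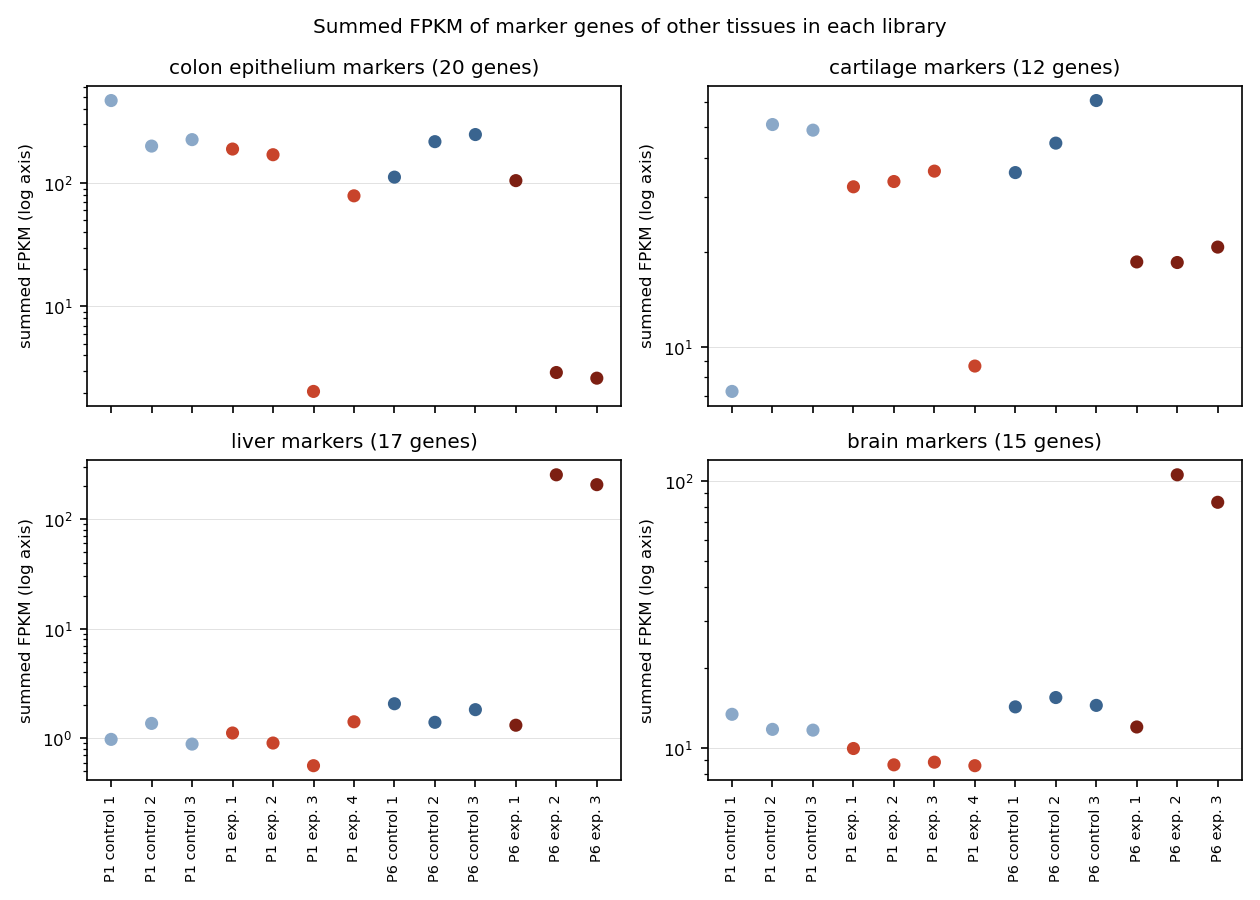
Summed FPKM (log axis) of marker genes of colon epithelium, cartilage, liver and brain in each of the 13 libraries, one dot per library, coloured by group. Passage 6 experimental libraries 2 and 3 reach 252 and 205 FPKM of liver markers, and their colon sums are 2.91 and 2.62 FPKM.

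The first comparison asks how the surviving cells differed from controls at passage 1. Acta2 was the named gene that rose most. This gene, which encodes smooth muscle alpha-actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand, GRCm38), was 15.7-fold higher, at 213 ± 13.3 against 12.7 ± 2.3 FPKM (mean ± SD, n = 4 and 3). The myosin light chain gene Myl9 (chromosome 2, 156775420 to 156781658, plus strand) was 8.43-fold higher, at 55.7 ± 4.82 against 5.72 ± 0.506 FPKM (mean ± SD, n = 4 and 3), and the enteric smooth muscle actin gene Actg2 6.82-fold higher. Igfbp2, an insulin-like growth factor binding protein gene (chromosome 1, 72824503 to 72852474), rose from 6.17 ± 0.512 to 45.7 ± 4.62 FPKM, and Ccl2, the gene of a monocyte-attracting chemokine (chromosome 11, 82035571 to 82037453), from 1.2 ± 0.13 to 11.4 ± 1.28 FPKM. Laminin genes Lamb2 and Lama5, the collagen-folding gene Fkbp10 and the immediate early gene Egr2 rose 3.3- to 3.51-fold. The hypoxia-induced gene Bnip3 rose 3.42-fold, at 63.1 ± 26.6 against 16.3 ± 0.932 FPKM (mean ± SD, n = 4 and 3).

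At passage 1 Lmo2, a transcription cofactor gene, fell 3.6-fold, the signalling adaptor gene Grap2 3.88-fold and the transcription factor gene Myb 2.84-fold. Procr, the endothelial protein C receptor gene (chromosome 2, 155751117 to 155755471), fell from 36.6 ± 1.29 to 10.2 ± 1.89 FPKM, and Lnp1 from 10.8 ± 1.36 to 1.25 ± 0.34 FPKM. Plxnc1, a semaphorin receptor gene, the anion transporter gene Slc26a4, the adhesion gene Icam2 and the RNase P subunit gene Rpp38 fell 2.15- to 2.4-fold. Cyp2c55, a cytochrome P450 gene, fell 2.77-fold. Its FPKM ordered the passage 1 libraries much as the colon sums did. They ran from 37.8 FPKM in control 1 (colon sum 468 FPKM) to 6.41 FPKM in experimental library 3 (2.04 FPKM). Only experimental libraries 2 and 4, at 9.53 and 10.2 FPKM, were in reverse order. Colon RNA may therefore make up part of the fall of Cyp2c55. For each of the 10 genes that fell and the 10 that rose most, every experimental library lay beyond every control library, as the rule for naming them required. Their adjusted p lay between 1.7e-06 and 0.00647 (limma, Benjamini-Hochberg).

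In total 3792 of 12469 genes changed at passage 1, 1434 higher and 2358 lower, and 71 of the higher and 45 of the lower genes changed at least 2-fold. Of the 3792 genes, 3747 showed no overlap between the groups, a pattern with a chance of 0.0571 for a gene with no difference. Genes called by adjusted p are already likely to show it, so it is no separate support. The share of higher genes was 37.8%, and it was 48.9% (1726 higher, 1805 lower) with equal FPKM totals, 51.7% (1861 and 1740) with median-of-ratios scaling and 50.2% (1827 and 1816) with quantile normalization, so the split by direction rests on the scaling. Between the libraries that carried cartilage transcripts, controls 2 and 3 against experimental libraries 1 to 3, 976 genes changed, 950 of them among the 3792, and Bnip3 and Cyp2c55 were no longer called. Leaving out control 1, 2 or 3 gave 2083, 2053 or 2087 genes.

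**Figure D2:**
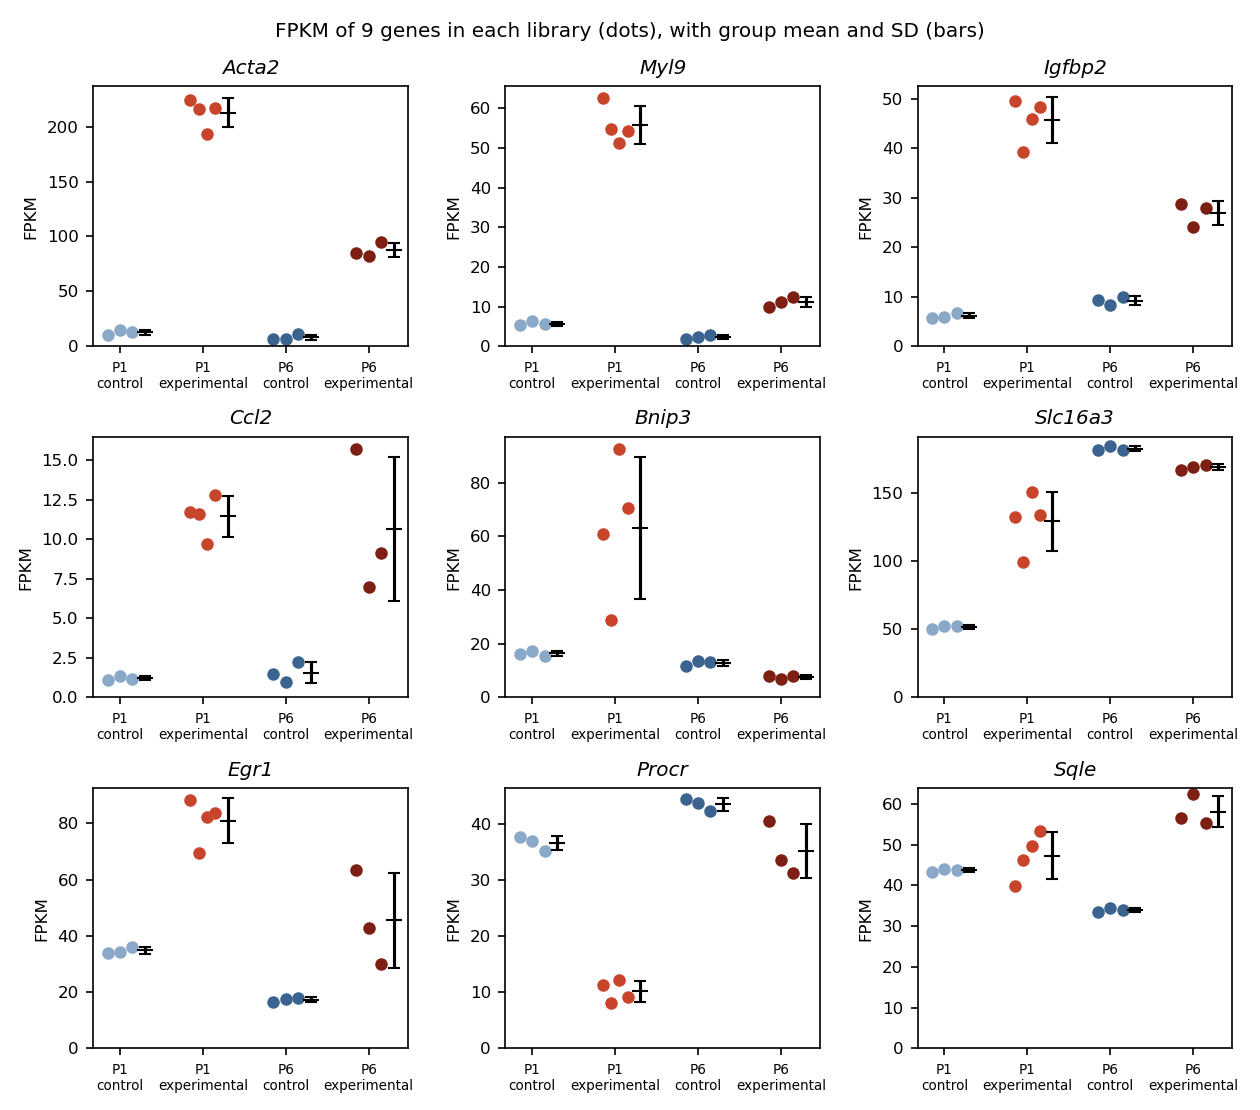
FPKM of 9 genes in each library (dots), with group mean and SD (bars), for control and experimental cells at passages 1 (P1) and 6 (P6). Acta2 lies at 213 ± 13.3 FPKM in P1 and 87.8 ± 6.66 FPKM in P6 experimental libraries, above every control library.

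Most glycolysis genes and some hypoxia genes were higher in experimental cells at passage 1. Of 20 glycolysis genes tested, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.66. The lactate exporter gene Slc16a3 rose 2.44-fold to 129 ± 21.7 FPKM, the lactate dehydrogenase gene Ldha 1.61-fold, the glucose transporter gene Slc2a1 1.99-fold and the phosphoglycerate kinase gene Pgk1 1.94-fold. The list gave adjusted p = 4.3e-10 in limma's camera with a preset correlation, and adjusted p = 0.509 with an estimated correlation. Of 22 hypoxia genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), among them the carbonic anhydrase gene Car12 at 2.47-fold and the adrenomedullin gene Adm at 2.19-fold. Their adjusted p was 2.7e-05, and adjusted p = 0.615 with an estimated correlation. The experimental libraries differed in both groups, with median log2 changes of 0.60, 0.23, 0.86 and 0.70 for glycolysis and 0.44, 0.15, 0.88 and 0.72 for hypoxia in libraries 1 to 4, and Slc2a1, Pgk1 and Adm were not called between the libraries with cartilage transcripts.

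Most immediate early and adhesion genes, and some mitosis genes, were also higher at passage 1. Of 26 immediate early genes, which respond quickly to growth and stress signals, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with Egr1 at 81 ± 8.01 against 34.8 ± 1.15 FPKM (mean ± SD, n = 4 and 3) and Egr3 and Ccn1 2.45- and 2.21-fold higher. Their adjusted p was 3.0e-11, and adjusted p = 0.509 with an estimated correlation. Of 36 adhesion and actin genes, 23 rose and 1 fell, the same counts adjusted over the list alone, including the integrin gene Itga3 at 2.42-fold and the annexin gene Anxa2 at 2.3-fold (adjusted p = 5.2e-12, adjusted p = 0.21 with an estimated correlation). Of 33 mitosis genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with the cyclin gene Ccnb1 1.38-fold and Ect2, needed for cytokinesis, 1.32-fold higher (adjusted p = 6.9e-08, adjusted p = 0.572 with an estimated correlation). Of 8 replication-dependent histone genes, 4 rose and 0 fell, as they did adjusted over the list alone (adjusted p = 0.00624, adjusted p = 0.509 with an estimated correlation). The histone list was fixed as a check of RNA quality, and whether its change comes from the cells or the libraries was not tested.

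In 4 further lists some members were higher at passage 1. Of 14 NF-kB and inflammation genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone), with Ccl2, the interleukin gene Il6 at 1.85-fold and the chemokine gene Cxcl1 at 1.77-fold (adjusted p = 0.0334, adjusted p = 0.509 with an estimated correlation). Of 27 extracellular matrix genes, 9 rose and 2 fell, as they did adjusted over the list alone, with the laminin gene Lamc1 1.67-fold and the fibronectin gene Fn1 1.63-fold higher. The matrix list had adjusted p = 0.00627, adjusted p = 0.702 with an estimated correlation, and adjusted p = 0.439 between the libraries with cartilage transcripts. Of 12 Wnt pathway genes, 5 rose, led by the receptor gene Fzd2 at 2.12-fold, and 2 fell, including the stem cell marker gene Lgr5, with the same counts adjusted over the list alone (adjusted p = 0.0334, adjusted p = 0.509 with an estimated correlation). Of 35 chromatin enzyme genes, 8 rose and 0 fell, also adjusted over the list alone, with the histone demethylase gene Kdm5b 1.57-fold higher (adjusted p = 0.0334, adjusted p = 0.509 with an estimated correlation). The matrix list was not called without control 1 (adjusted p = 0.12), nor the Wnt and chromatin lists without experimental library 2 (adjusted p = 0.0754 and 0.0754). With median-of-ratios scaling the NF-kB and Wnt lists had adjusted p = 0.0605 and 0.0586. With a minimum of 5 FPKM the Wnt and chromatin lists had 0.346 and 0.301, and with the colon and cartilage sums as covariates the NF-kB and chromatin lists had 0.082 and 0.0522.

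Some lysosomal, chaperone, ribosomal protein and noncoding RNA genes were lower at passage 1. The ribosomal protein and noncoding RNA lists were fixed as checks of RNA quality. Of 28 autophagy and lysosome genes, 11 fell and 1 rose, as they did adjusted over the list alone, with the cathepsin gene Ctsd at 387 ± 22.2 against 590.0 ± 11.2 FPKM (mean ± SD, n = 4 and 3) and Ctsa 1.5-fold lower (adjusted p = 0.0334, adjusted p = 0.572 with an estimated correlation). Of 22 heat shock genes, 5 fell and 0 rose, also adjusted over the list alone, including the chaperone genes Hspa8 at 1.26-fold and Hsp90aa1 at 1.33-fold lower (adjusted p = 0.0343, adjusted p = 0.65 with an estimated correlation). Of 47 ribosomal protein genes, 13 fell and 1 rose, also adjusted over the list alone, with Rpl6 1.21-fold lower (adjusted p = 0.0334, adjusted p = 0.867 with an estimated correlation). Of 7 nuclear-retained noncoding RNAs, 4 fell and 0 rose, also adjusted over the list alone, with Malat1 1.63-fold lower (adjusted p = 0.0334, adjusted p = 0.509 with an estimated correlation). The heat shock and ribosomal lists were not called with median-of-ratios scaling (adjusted p = 0.0727 and 0.233), nor heat shock with the colon and cartilage sums as covariates (0.197). Calls also ended for heat shock without experimental library 3 (adjusted p = 0.0648), and for autophagy without experimental library 1 or 2 (0.059 and 0.107). They ended for ribosomal proteins without control 3 or experimental library 2 (0.101 and 0.103) and for noncoding RNAs between the libraries with cartilage transcripts (0.0536), without control 1 or experimental library 2 (0.0653 and 0.0566).

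Neuronal genes moved in both directions at passage 1. Of 24 neuronal cytoskeleton and identity genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone, list adjusted p = 0.876). The heavy neurofilament gene Nefh fell from 66.8 ± 3.11 to 33.2 ± 3.56 FPKM, the secretory granule gene Chgb from 236 ± 7.82 to 149.5 ± 12.9 FPKM and the growth cone gene Gap43 1.38-fold, while the synaptic vesicle gene Syn1 fell 1.33-fold. Of the cold-inducible RNA-binding protein genes, Cirbp was at 20.8 ± 2.45 against 26.2 ± 1.29 FPKM (mean ± SD, n = 4 and 3) (adjusted p = 0.0261) and Rbm3 at 106 ± 13.4 against 113 ± 2.06 FPKM (mean ± SD, n = 4 and 3) (adjusted p = 0.474, limma). The call for Cirbp ended without control 1, 2 or 3 (adjusted p = 0.0871, 0.0963 and 0.053) and without experimental library 4 (0.0665). The 8 tested markers of epithelial cells had a median log2 change of -1.11 with 0 higher and 1 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.112), in libraries whose colon sums ran from 2.04 to 468 FPKM.

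The second comparison asks which differences were present at passage 6, when the cells looked normal. Acta2 was again the named gene that rose most, 9.84-fold, at 87.8 ± 6.66 against 8.2 ± 2.36 FPKM (mean ± SD, n = 3 and 3). Ccl2 was 4.4-fold higher at 10.6 ± 4.55 against 1.57 ± 0.634 FPKM (mean ± SD, n = 3 and 3), Myl9 3.64-fold, Fkbp10 3.37-fold and Igfbp2 2.74-fold, and the growth factor binding protein gene Igfbp5 rose from 11.1 ± 0.288 to 31.6 ± 2.39 FPKM. The leucine-rich repeat gene Lrrn2 rose 2.23-fold. Egr1 was at 45.5 ± 16.8 against 17.3 ± 0.855 FPKM (mean ± SD, n = 3 and 3), Rn7sk, a small nuclear RNA gene, at 10.8 ± 6.39 against 2.32 ± 0.721 FPKM (mean ± SD, n = 3 and 3), and Sparcl1, a matrix-associated glycoprotein gene, at 15.5 ± 6.75 against 6.34 ± 0.779 FPKM (mean ± SD, n = 3 and 3), with calls that ended when single libraries were left out. Sparcl1 was at 7.99 FPKM in experimental library 1, near the controls at 5.47 to 6.98 FPKM, and at 21 and 17.6 FPKM in libraries 2 and 3, which carried brain and liver transcripts. Without control 1, 2 or 3 the adjusted p was 0.0509, 0.0665 and 0.0524 for Rn7sk and 0.118, 0.109 and 0.138 for Sparcl1. Without experimental library 2 or 3 it was 0.124 and 0.133 for Sparcl1, and without control 1 or 2 0.0509 and 0.0503 for Egr1.

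The 10 genes that fell most at passage 6, among those with a mean of at least 5 FPKM and no overlap between the groups, were genes of cartilage or mucosal epithelium. Col2a1, the cartilage collagen gene (chromosome 15, 97975602 to 98004695), was at 11.8, 15.8 and 24.9 FPKM in controls and at 0.179, 0.304 and 0.325 FPKM in experimental libraries. Krt8, a keratin gene of simple epithelia, was at 11, 25.1 and 26.6 FPKM in controls and at 10.8, 0.456 and 0.373 FPKM in experimental libraries, so that experimental library 1 lay close to the lowest control. The mucosal genes Dmbt1, Zg16, Muc13, Reg3b, Sprr2a1, Pigr, Guca2a and Ceacam1 had log2 changes of -3.31 to -2.24, with adjusted p between 0.0303 and 0.0467 (limma). These calls ended for all 8 genes without control 2 (adjusted p = 0.098 to 0.139) or control 3 (0.0985 to 0.132). They ended too without experimental library 2 (0.0929 to 0.135) or 3 (0.089 to 0.129), and without control 1 for the 7 other than Reg3b (0.0544 to 0.101). Krt8, with adjusted p = 0.0498, lost its call without control 1, 2 or 3 (adjusted p = 0.0845, 0.142 and 0.14) and without experimental library 2 or 3 (0.144 and 0.136). Of 8 epithelial markers, 7 fell and 0 rose (8 and 0 adjusted over the list alone, list adjusted p = 0.00157, adjusted p = 0.456 with an estimated correlation). The list had adjusted p = 0.052 without experimental libraries 2 and 3, whose colon sums were 2.91 and 2.62 FPKM against 105 FPKM in library 1, and adjusted p = 0.0632 with the colon sum as a covariate.

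In total 2462 of 12458 genes changed at passage 6, 1119 higher and 1343 lower, of which 29 and 88 changed at least 2-fold. The counts were 1144 higher and 1057 lower with equal FPKM totals, 1358 and 1111 with median-of-ratios scaling and 1259 and 1105 with quantile normalization, so which direction holds more genes rests on the scaling. In all 2462 every experimental library lay beyond every control library, which has a chance of 0.1 for a gene with no difference. Calling by adjusted p already favours this pattern, so it is no separate support. Leaving out control 1, 2 or 3 gave 767, 670 or 749 genes, leaving out experimental library 1 gave 4257 and leaving out experimental library 3 gave 1582. Without experimental libraries 2 and 3, which carried liver and brain transcripts, library 1 alone against the 3 controls gave 2460 genes, 1567 of them among the 2462, under the assumption that the lone library varies like the controls. Library 1 also stands apart from the controls in its cartilage sum, 18.6 against 35.8 to 60.7 FPKM. With the colon sum as a covariate 1139 genes changed, 817 of them among the 2462. That sum was 2.91 and 2.62 FPKM in experimental libraries 2 and 3, against 105 FPKM in library 1 and 112 to 248 FPKM in controls. The covariate thus mostly sets libraries 2 and 3 apart, and is no separate check beside leaving them out.

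Most sterol and fatty acid synthesis genes were higher at passage 6. Of 25 cholesterol biosynthesis genes, 18 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.47. Sqle, the squalene epoxidase gene (chromosome 15, 59315077 to 59331192), was at 58.2 ± 3.8 against 34 ± 0.50 FPKM (mean ± SD, n = 3 and 3), the sterol dehydrogenase gene Nsdhl rose 1.9-fold, the farnesyl diphosphate synthase gene Fdps 1.62-fold and the sterol oxidase gene Msmo1 1.57-fold. The list had adjusted p = 3.7e-12 in limma's camera, and adjusted p = 0.413 with an estimated correlation. Its median log2 change was 0.36 in experimental library 1, the only one without liver and brain transcripts. It was 0.57 and 0.42 in libraries 2 and 3. Of 16 fatty acid synthesis genes, 11 rose and 0 fell (13 and 1 adjusted over the list alone), with the desaturase genes Fads2 and Scd2 1.47- and 1.36-fold and the elongase gene Elovl6 1.34-fold higher (adjusted p = 2.6e-07, adjusted p = 0.413 with an estimated correlation).

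Some synaptic and neuronal genes were higher at passage 6, in data where 2 of the 3 experimental libraries carried brain transcripts. Of 23 synapse genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including the synaptophysin gene Syp at 1.39-fold. The list had adjusted p = 5.4e-04, adjusted p = 0.456 with an estimated correlation and adjusted p = 0.476 without experimental libraries 2 and 3, whose brain marker sums were 106 and 83.3 FPKM against 12 FPKM in library 1. Syp itself was at 28, 33.5 and 30.9 FPKM in experimental libraries 1 to 3, all above the controls at 20.8 to 22.5 FPKM. Of 24 neuronal cytoskeleton and identity genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with the microtubule regulator gene Stmn3 1.24-fold higher. The neuronal list had adjusted p = 0.0106, adjusted p = 0.45 with an estimated correlation, and adjusted p = 0.356 without libraries 2 and 3. With the colon sum as a covariate the synapse and neuronal lists had 0.903 and 0.689. Of 12 progenitor and Notch genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with the receptor gene Notch2 1.36-fold and the differentiation inhibitor gene Id1 1.35-fold lower (adjusted p = 0.0179, adjusted p = 0.413 with an estimated correlation).

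Some adhesion, Wnt and lysosomal genes were higher at passage 6. Of 37 adhesion and actin genes, 12 rose and 4 fell (14 and 4 adjusted over the list alone), with Itga3 1.83-fold higher, and with the epithelial cadherin gene Cdh1, one of the colon markers, among those that fell (adjusted p = 0.00157, adjusted p = 0.45 with an estimated correlation). The call for Cdh1 ended without control 2 or 3 (adjusted p = 0.0815 and 0.0796) and without experimental library 2 or 3 (0.0708 and 0.070). Of 11 Wnt pathway genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Fzd2 1.76-fold and the ligand gene Wnt5a 1.64-fold higher. The Wnt list had adjusted p = 0.0197, adjusted p = 0.45 with an estimated correlation, and adjusted p = 0.221 without experimental libraries 2 and 3. Of 28 autophagy and lysosome genes, 6 rose and 2 fell (11 and 2 adjusted over the list alone), with the lysosomal membrane gene Lamp1 at 619 ± 10.6 against 439 ± 7.1 FPKM (mean ± SD, n = 3 and 3) (adjusted p = 0.0332, adjusted p = 0.413 with an estimated correlation). Of 29 NRF2 oxidative stress genes, 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0305, adjusted p = 0.413 with an estimated correlation). Of 7 replication-dependent histone genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, list adjusted p = 0.0498, adjusted p = 0.456 with an estimated correlation). Without control 1 the NRF2, autophagy and histone lists had adjusted p = 0.0889, 0.0573 and 0.0952. Without experimental library 2 autophagy and histones had 0.054 and 0.0915, and without control 2 or experimental library 1 histones had 0.0593 and 0.108. With a minimum of 5 FPKM the NRF2, autophagy and Wnt lists had 0.155, 0.088 and 0.088, with median-of-ratios scaling histones had 0.0828, and with the colon sum as a covariate Wnt had 0.284.

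A minority of chromatin, noncoding RNA, ribosomal protein and mitosis genes were lower at passage 6. Of 35 chromatin enzyme genes, 7 fell and 0 rose, also adjusted over the list alone, with the histone deacetylase gene Hdac5 1.25-fold lower (adjusted p = 0.0219, adjusted p = 0.458 with an estimated correlation, and adjusted p = 0.131 without experimental library 1). The call for Hdac5 ended without control 1, 2 or 3 (adjusted p = 0.0534, 0.0554 and 0.0546). Of 7 nuclear-retained noncoding RNAs, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with Malat1 1.36-fold lower and Xist, the X inactivation RNA, at 35.7 ± 2.89 against 49.7 ± 0.666 FPKM (mean ± SD, n = 3 and 3). The list had adjusted p = 0.0219, adjusted p = 0.45 with an estimated correlation, adjusted p = 0.0552 without experimental library 3 and 0.113 without libraries 2 and 3. Of 47 ribosomal protein genes, 4 fell and 1 rose (2 and 1 adjusted over the list alone), with Rpl10a 1.23-fold lower (adjusted p = 0.00261, adjusted p = 0.749 with an estimated correlation). Without experimental library 3 the ribosomal list had adjusted p = 0.108 in limma's camera. It was higher instead of lower without libraries 2 and 3, where library 1 alone had a median log2 change of 0.050. It was also higher with the colon sum as a covariate (adjusted p = 0.00219), which mostly sets libraries 2 and 3 apart. Of 33 mitosis genes, 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0498, adjusted p = 0.685 with an estimated correlation). Without control 1 or 3 the mitosis list had adjusted p = 0.0952 and 0.0623. Without experimental library 2 or 3 it had 0.134 and 0.0957, without both 0.564, and with median-of-ratios scaling 0.107. With the colon sum as a covariate the noncoding RNA and mitosis lists had 0.288 and 0.673. Cirbp was at 14.7 ± 2.02 against 20.2 ± 1.13 FPKM (mean ± SD, n = 3 and 3) (adjusted p = 0.0214) and Rbm3 at 51.2 ± 4.81 against 55.1 ± 2.11 FPKM (mean ± SD, n = 3 and 3) (adjusted p = 0.326, limma). The Cirbp call ended without control 1, 2 or 3 (adjusted p = 0.0582, 0.0865 and 0.076) or without experimental library 2 (0.0588).

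**Figure D3:**
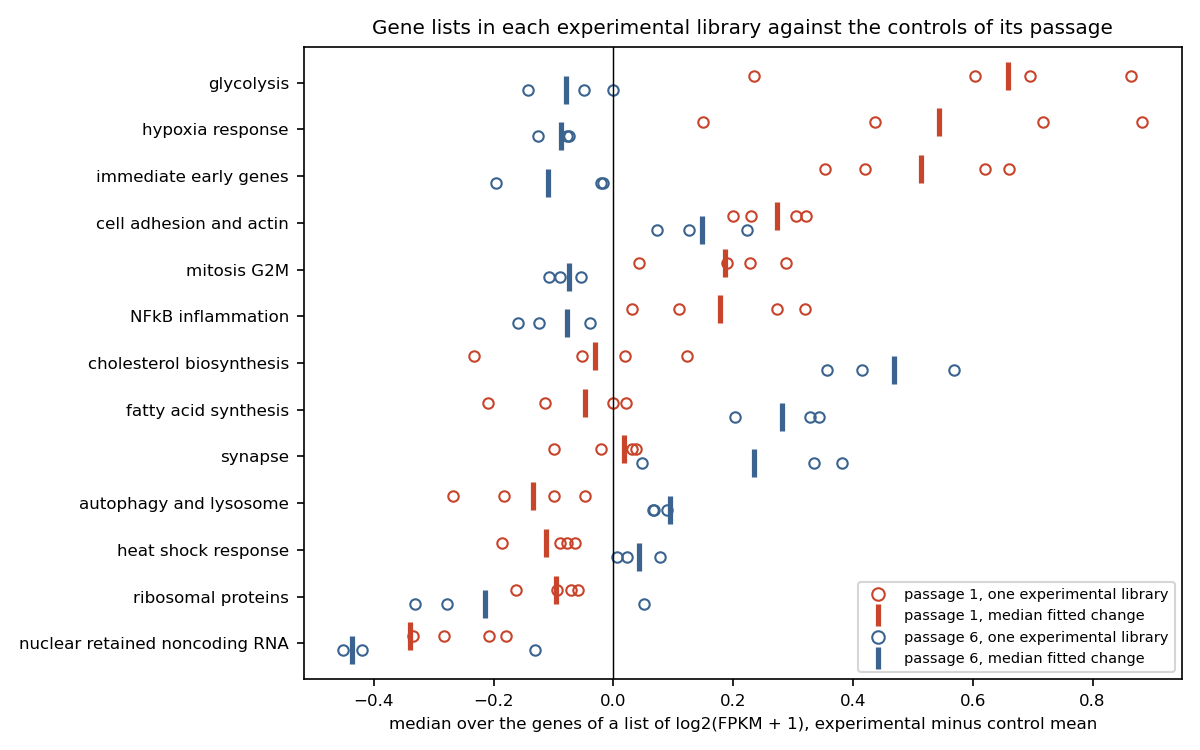
Median over the genes of a list of log2(FPKM + 1) in each experimental library minus the control mean (circles, 4 libraries at passage 1 and 3 at passage 6), with the median fitted log2 fold change (bars). Glycolysis has a fitted median of 0.66 at passage 1 and -0.079 at passage 6, and cholesterol biosynthesis -0.030 and 0.47.

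The third comparison tests the change at passage 6 against the change at passage 1. Bnip3, which was 3.42-fold higher at passage 1, was 1.59-fold lower at passage 6, a difference of -2.44 ± 0.40 (SE) on the log2 scale with adjusted p = 0.0027 in limma. The calcium-dependent membrane gene Anxa2 had a difference of -1.74 (adjusted p = 2.7e-04) and the respiratory chain subunit gene Cox4i2 of -1.76 (adjusted p = 0.00332). The selenium-binding protein gene Selenbp1 had one of -1.95 (adjusted p = 0.018) and the microRNA gene Mir6910 of -1.64 (adjusted p = 0.0184). In the other direction, Procr, lower at passage 1, had a difference of 1.46 (adjusted p = 5.5e-04) and Nefh of 1.20 (adjusted p = 1.9e-04). Plxnc1 had one of 1.12 (adjusted p = 1.0e-05), the chaperone gene Clu of 1.17 (adjusted p = 0.00349) and Sparcl1 of 1.61 (adjusted p = 0.00766). Acta2, higher at both passages, differed by -0.67 on the log2 scale (adjusted p = 0.0494), while Fkbp10 and Ccl2 differed by -0.053 (adjusted p = 0.849) and -0.36 (adjusted p = 0.469). Over the 13 libraries 1918 of 13019 genes differed in their change, 1102 more positive and 816 more negative at passage 6. Leaving out passage 1 control 1, 2 or 3 gave 1185, 1227 or 1183 genes, and leaving out passage 6 control 1, 2 or 3 gave 1160, 1204 or 1216. Without passage 6 experimental libraries 2 and 3 the count was 1372, Selenbp1 was not called and the difference for Sparcl1 was 0.83.

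Many glycolysis, hypoxia and immediate early genes had a more negative change at passage 6, and many sterol genes a more positive one. The gene lists were tested on this contrast as an addition chosen after seeing the data. Of 20 glycolysis genes, 13 were more negative and 0 more positive at passage 6 (15 and 1 adjusted over the list alone, list adjusted p = 3.1e-09, adjusted p = 0.324 with an estimated correlation). For hypoxia the counts were 12 and 1 of 22 (14 and 1 adjusted over the list alone, list adjusted p = 2.2e-06, adjusted p = 0.422 with an estimated correlation). They were for immediate early genes 13 and 0 of 26 (15 and 0 adjusted over the list alone, 2.8e-09, adjusted p = 0.215 with an estimated correlation) and for mitosis 15 and 0 of 33 (22 and 0 adjusted over the list alone, 1.0e-10, adjusted p = 0.324 with an estimated correlation). Of 25 cholesterol biosynthesis genes, 14 were more positive and 0 more negative (16 and 0 adjusted over the list alone, list adjusted p = 8.8e-09, adjusted p = 0.324 with an estimated correlation).

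The last comparison counts the changes shared by both passages. Acta2, Myl9, Igfbp2, Ccl2, Fkbp10 and Fzd2 rose at both, and Slc18a2, the vesicular monoamine transporter gene, fell at both, from 23.8 ± 0.919 to 11.8 ± 1.89 FPKM and from 47.6 ± 0.55 to 34.1 ± 1.85 FPKM. Of 11908 genes tested at both passages, 372 rose at both against 128 for independent lists (exact one-sided hypergeometric p = 3.5e-95). The genes that fell at both numbered 475 against 240 (exact p = 3.7e-61). The hypergeometric test takes genes as independent draws, which they are not, so it does not measure replication between libraries. The shared higher and lower genes numbered 415 and 316 with equal FPKM totals, 513 and 315 with median-of-ratios scaling and 469 and 323 with quantile normalization. In opposite directions 126 genes were called, 36 higher then lower and 90 lower then higher. Of 3663 genes called at passage 1, 2598 (70.9%) had the same sign at passage 6 and 847 (23.1%) were called in the same direction there. Of 103 genes with at least a 2-fold change at passage 1, 66 were called in the same direction and 3 in the opposite one at passage 6, and the median ratio of their log2 changes was 0.514. Across genes, which are not independent replicates, the log2 changes of the passages had Pearson r = 0.466 and Spearman rho = 0.324. The 847 genes became 335, 307 or 333 without passage 6 control 1, 2 or 3 and 543 without passage 6 experimental library 3, and 722 without experimental libraries 2 and 3 together. They became 410 with the colon and cartilage sums as covariates, 343 with the passage 1 libraries with cartilage transcripts only, 388 without a filter and 1406 with array weights.

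**Figure D4:**
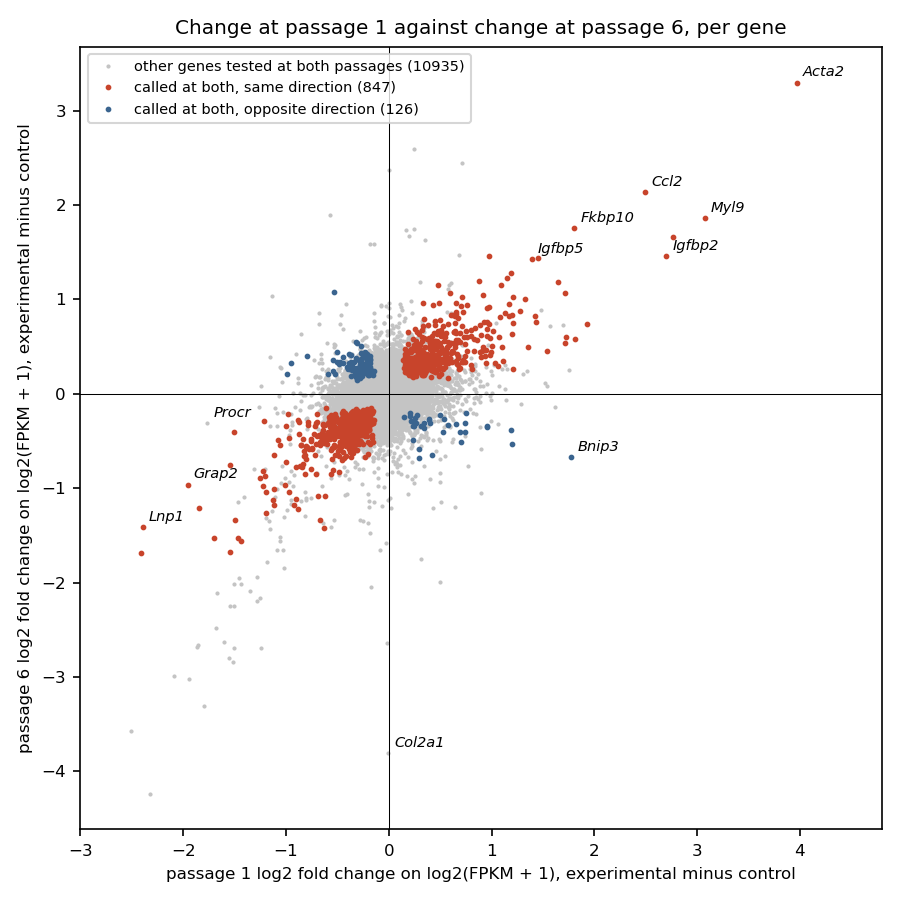
Log2 fold change on log2(FPKM + 1), experimental minus control, at passage 1 (horizontal) and passage 6 (vertical), one dot per gene tested at both passages. The 847 genes called in the same direction are red and the 126 called in opposite directions are blue, and Acta2 lies farthest to the upper right at 3.97 and 3.30.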

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

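The tests of the colon, liver and brain markers, and the test of gene lists on the difference between passages, were chosen after the result was seen. Some values stood far from the other 3 passage 1 experimental libraries, where the gap to the nearest library divided by the range exceeded Dixon's 95% critical value. Library 4 was low in the summed cartilage markers (ratio 0.857), the summed bone and connective tissue markers (0.848), the glial receptor gene Erbb3 (0.858) and the transcription factor gene Myb (0.944), and high in the death receptor gene Fas (0.910). Library 1 was high in the Wnt receptor gene Fzd2 (0.986) and the intermediate filament gene Nes (0.877), and library 3 was high in the secreted glycoprotein gene Stc2 (0.935). These are 8 of 161 groups of values tested, and chance alone gives about 8.05.

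A tested difference between the effects at passages 6 and 1 set apart 1918 genes, and 10 named ones among them. On the log2 scale it was 1.61 for Sparcl1, 1.46 for Procr, 1.20 for Nefh, 1.17 for Clu and 1.12 for Plxnc1, and -2.44 for Bnip3, -1.95 for Selenbp1, -1.76 for Cox4i2, -1.74 for Anxa2 and -1.64 for Mir6910. Among 100 relabellings drawn within passages, 2 gave at least 1918 genes, the real one included, and the highest other gave 3344. The relabelling with 3344 genes grouped passage 1 experimental library 2 with the 3 passage 1 controls against the other experimental libraries. It kept the passage 6 groups, which turns the passage 1 change nearly around, so that the 2 changes add up in the contrast. Relabelling removes the change at each passage along with any difference between them. It therefore cannot decide whether equal changes at both passages would give 1918 genes by chance.

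Of 33 gene lists tested on the difference between passages, limma's camera at the preset correlation called 15. The median difference was positive in 6 of these called lists. It was 0.42 for cholesterol biosynthesis (adjusted p = 0.324 with an estimated correlation), 0.29 for synapse (0.559), 0.28 for fatty acid synthesis (0.324), 0.17 for heat shock (0.324), 0.16 for autophagy and lysosome (0.178) and 0.16 for neuronal genes (0.382). It was negative in the other 9 called lists: -0.67 for glycolysis (adjusted p = 0.324 with an estimated correlation), -0.63 for hypoxia (0.422), -0.55 for immediate early genes (0.215), -0.30 for progenitor and Notch genes (0.0639), -0.28 for NF-kB genes (0.113), -0.27 for mitosis (0.324), -0.24 for adhesion and actin (0.215), -0.21 for chromatin enzymes (0.178) and -0.13 for extracellular matrix (0.712).

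Colon transcripts differed between libraries of the same group. Over the 7 passage 1 libraries the colon markers rose and fell together, with a median pairwise Pearson r of 0.973 on the log scale, which may reflect RNA of another tissue in some libraries. The controls, which had no storage failure, carried colon sums of 200 to 468 FPKM at passage 1 and 112 to 248 FPKM at passage 6. This argues against a response of the cells to the failure as the source of the colon transcripts in controls and their spread there. For the lower sums in experimental libraries such a response stays open. The highest colon sum among the 4 passage 1 experimental libraries was 92.5 times the lowest, but a response that varies between vials would also give such a range. The sums were 110.0 ± 86.6 FPKM in experimental and 298 ± 148 FPKM in control libraries at passage 1 (exact permutation p = 0.0571), and 36.8 ± 58.9 and 192 ± 71.3 FPKM at passage 6 (exact p = 0.10). When that RNA entered, whether it was RNA or sequencing reads of other samples, and whether it marks batches of preparation or sequencing, which the labels do not give, was not tested.

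Liver and brain transcripts stood out in passage 6 experimental libraries 2 and 3. Of the 32 liver and brain markers, 31 lay above all other 11 libraries in both, which may reflect RNA of other tissues in these libraries. Neuronal differentiation is excluded as the cause of the whole pattern, since 17 of 17 liver markers did so too. The marker test does not separate a small neuronal change from brain RNA in the synapse and neuronal lists at passage 6, whose adjusted p without these libraries was 0.476 and 0.356. If such transcripts mark batches, part of the differences between the passage 6 groups could be differences between batches, since no control of that passage carries the liver transcripts, and the cartilage sums, 18.5 to 20.8 FPKM in experimental libraries 1 to 3 and 35.8 to 60.7 FPKM in controls, set library 1 apart from the controls too.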

How the results depend on the processing

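The tests of library subsets, of the covariates, of exon length and of permuted list medians were chosen after the result was seen. Where no cause is given below, the cause was not tested. With replicate block, the replicate number as a block, 1813 genes changed at passage 1, 1438 at passage 6, 728 differed between passages and 379 were shared, but the numbers do not pair the libraries: control and experimental libraries of one number had residual correlations of 0.17, -0.19 and 0.24 at passage 1 and -0.066, -0.060 and 0.033 at passage 6. Without a filter, 1286 genes changed at passage 6, 1185 differed between passages and 388 were shared. Array weights gave 3192 differing and 1406 shared genes. The colon covariate gave 1139 genes at passage 6 and, with the covariates at both passages, 410 shared genes. The libraries with cartilage transcripts, with 2 fewer libraries, gave 976 genes at passage 1 and 343 shared genes.

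Leaving out 1 library in turn gave 2053 to 4069 genes at passage 1, 670 to 4257 at passage 6, 1160 to 2547 differing and 307 to 1263 shared genes, and 9 to 14 lists at passage 1, 11 to 17 at passage 6. Of the 14 lists called at passage 1 and 15 at passage 6, camera with an estimated correlation called 0 and 0. The rotation test fry called 14 and 13 of all 33 lists, but not 9 of these 29. They are hypoxia (adjusted p = 0.0809) and extracellular matrix (0.142) at passage 1, and at passage 6 synapse (0.0946), neuronal genes (0.0802), ribosomal proteins (0.235), chromatin enzymes (0.0648), mitosis (0.0955), histones (0.102) and epithelial markers (0.0546). An exact permutation of list medians called 0 at passage 1, where 8 lists had the smallest p that 35 splits allow. The ribosomal proteins at passage 6 reversed, to higher, without experimental libraries 2 and 3 (adjusted p = 0.0435, the lone library assumed to vary like the controls) and with the colon covariate (adjusted p = 0.00219).

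For single named genes, 5308 comparisons with an alternative kept direction and side of the threshold, 949 were weaker, 4 stronger and 0 reversed, and for lists 345 kept both, 113 were weaker and 2 reversed. Calls held under every alternative run for 68 of 142 named genes at passage 1, 46 of 135 at passage 6 and 8 of 10 for the difference. Unknown depth limits what can be said of genes near 1 FPKM, since low values with few reads cannot be told from precise ones.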

Other observations

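The tests of Acta2 against smooth muscle and colon RNA, and the counts by gene class, were chosen after the result was seen. Genes of the sympathoadrenal lineage moved in both directions. At passage 1 Slc18a2, which loads monoamines into vesicles, was at 11.8 ± 1.89 against 23.8 ± 0.919 FPKM (mean ± SD, n = 4 and 3), while the transcription factor genes Isl1 and Mycn rose 1.87- and 1.8-fold and the neurotrophin receptor gene Ngfr 1.4-fold. At passage 6 Dbh, the noradrenaline synthesis gene, was at 4.58 ± 0.819 against 8.35 ± 0.40 FPKM (mean ± SD, n = 3 and 3), and Isl1 and Ngfr were 1.37- and 1.35-fold higher. Of 16 genes of the list 4 rose and 3 fell at each passage (6 and 3 at passage 1, 4 and 7 at passage 6 adjusted over the list alone), with list adjusted p = 0.187 and 0.759 in limma's camera. Of the amino acid stress genes controlled by ATF4, different ones are named at the 2 passages. Cth, for cysteine synthesis, fell from 16.9 ± 0.699 to 9.68 ± 1.91 FPKM at passage 1 and was not called at passage 6. Chac1, a glutathione-degrading enzyme gene, fell from 24.3 ± 0.947 to 14.8 ± 1.87 FPKM and Ddit3, the stress transcription factor CHOP, from 26.3 ± 2.01 to 16.9 ± 1.72 FPKM at passage 6, and neither was called at passage 1. Of 28 genes 1 rose and 8 fell at passage 1, and 3 rose and 8 fell at passage 6. The counts were the same adjusted over the list alone (list adjusted p = 0.469 and 0.103 in limma's camera). At passage 1 the list moved in opposite directions within the experimental group. Its median log2 change was -0.24, -0.35, 0.17 and 0.14 in libraries 1 to 4. Ddit3 was at 35.1, 27.5, 53.4 and 51.9 FPKM in them, against 39.4 to 41.4 FPKM in controls.

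Where noncoding RNA genes of 4 classes changed, most were lower. At passage 6, 16 of 22 mitochondrial tRNA genes fell and 0 rose, 28 small nucleolar RNA genes fell and 1 rose, 18 microRNA genes fell and 2 rose, and 26 long intergenic RNA genes fell and 2 rose. At passage 1, 44 long intergenic RNA genes fell and 7 rose, 7 small nucleolar RNA genes fell and 0 rose, and 6 mitochondrial tRNA genes fell and 3 rose, in data where 37.8% of all changed genes were higher. With median-of-ratios scaling the long intergenic RNA genes numbered 35 lower and 10 higher at passage 1 and 25 and 4 at passage 6, and the small nucleolar RNA genes 6 and 1, and 28 and 1. How many fragments stand behind the FPKM of such short transcripts in poly(A)-selected libraries is unknown. Across all tested genes the log2 change had Spearman rho = 0.117 with exon length and 0.0448 with GC content at passage 1, and 0.0151 and 0.207 at passage 6.

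Acta2, Myl9 and Actg2, genes of contractile cells, rose at both passages. The summed 7 smooth muscle markers, which leave out these 3 genes, rose by 1.05% of the rise of Acta2 at passage 1. They summed to 2.21 to 2.46 FPKM in controls and 4.06 to 4.93 FPKM in experimental libraries. This argues against smooth muscle tissue RNA as the main source of Acta2, as far as these markers represent that tissue. In the 3 experimental libraries with a colon sum under 10 FPKM, Acta2 was 12.9, 7.58 and 8.73 times the highest control of its passage. This argues against RNA that comes with colon epithelium as the source of Acta2 there. The colon markers are of epithelium, so they do not test RNA of other parts of the colon. A hypothesis is activity of SRF and MRTF, transcription factors regulated by actin: 23 of their targets outside the fixed lists had a median log2 change of 0.28 at passage 1 (12 higher and 2 lower, camera p = 7.6e-08, p = 0.0023 with an estimated correlation), which is consistent with it. At passage 6 the median over 22 targets was 0.058 (6 higher and 1 lower, camera p = 0.025, p = 0.18 with an estimated correlation), which leaves it open there.

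Among 100 relabellings drawn within passages only the real one, 1 in all, gave as many as the 847 shared changes, and the highest other gave 19. Relabelling removes the changes at each passage along with their overlap. The other splits gave at most 152 genes at passage 1 and 1 gene at passage 6, which left few to share. The relabellings therefore cannot decide whether the overlap arose by chance, and they do not test differences between cultures or batches. The largest median log2 shift of a chromosome present at both passages was 0.0488, for chromosome 10. Chromosome 1 shifted by 0.093 at passage 1 and 0.046 at passage 6. These values argue against a whole chromosome gained or lost in most cells as a general cause of the persistence. A gain or loss in a minority of cells would shift the median little, so its selection stays open. Smaller gains, and selection of cells already different before freezing, were not tested.

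For the 3792 genes at passage 1, 1 of 35 splits of the libraries, the real one, gave as many, and the highest other gave 152. The real groups thus stand apart from the other splits. The splits take libraries as independent, while replicates may come from 1 culture. They therefore cannot exclude a chance difference between cultures or batches. For the 14 gene lists at passage 1 the real groups do not stand apart, as 18 of 35 splits gave at least as many and the highest other gave 20. At passage 6 the 10 splits are too few for a share under 0.05: the real split, 1 of 10 with as many, gave 2462 genes and 15 lists, and the highest other 1 gene and 13 lists.

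Bone and connective tissue markers reached 149 and 134 FPKM in passage 6 experimental libraries 2 and 3 and at most 13 FPKM elsewhere, and Y-linked genes 0.388 and 0.297 FPKM in the same 2 libraries. Erythroid markers summed to between 0.0628 and 30.0 FPKM. The highest sums of the remaining lists were 15.5 FPKM for pancreas, 10.4 for skeletal muscle, 8.97 for heart, 5.15 for smooth muscle, 3.11 for lung, 0.70 for lymphoid cells, 0.520 for testis and 0.132 for kidney.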
